A study of Mus musculus with 8 samples.

How the data were processed

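Expression was measured with 1-colour Affymetrix mouse Gene 2.0 ST arrays in dorsal and ventral aortic tissue of mouse embryos at embryonic day 12.5, with 4 arrays per tissue. Per the labels' protocols, unfixed embryos were frozen and sectioned, both tissues were laser microdissected from the same embryos, and 200 to 1000 pg of total RNA was amplified with the Ovation Pico system (single primer isothermal amplification) before biotin labelling. Amplification from so little RNA can add spread between arrays, most of all for weakly expressed genes.

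The deposited values are on the log2 scale. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, which corrects background, makes the probe distributions of the arrays equal and summarises probes. No version of either is given in the sources used here. The array medians lay between 3.59 and 3.65 on all 8 arrays, so values were not centred per gene. Because RMA equalises the arrays, a difference is relative to the other genes on the array and says nothing of total RNA. The table holds 25429 rows named by Entrez gene number, which points to a gene-based definition of the array whose name and version are not given. The platform table paired 24675 rows with 1 gene symbol, 0 with several and 754 with none. These 754 are unnamed here and were not used. Symbols were updated through the Entrez number with a RefSeq gene table of assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other, since the build behind the array definition is not stated. Each named gene had 1 row.

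Genes were tested if their value exceeded the array's median over all rows on at least 4 of the 8 arrays. This left 12416 genes, 50.3% of the named ones. Genes above it on fewer arrays were not tested, but levels of T cell genes and of T cell receptor segments under that filter are used where Trac is discussed, and said to be so there. No further normalization was applied. No slide or scan date is given in the sources used here, so no such batch was fitted. The fit used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust estimation), with the replicate number as a fixed block and tissue as the effect, a two-sided moderated test of ventral minus dorsal, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 without a minimum difference. It leaves 3 residual degrees of freedom per gene before moderation.

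The replicate number was kept as a block because the labels say that both tissues came from the same embryos and use the numbers 1 to 4 in each tissue. The labels do not state that a number marks 1 embryo. After the data were in hand, deviations of same-numbered arrays from their tissue means correlated across genes at r = 0.11, 0.03, 0.02 and 0.12, against -0.13 to 0.10 for arrays of different numbers. Only 2 of the 4 exceed 0.1, short of the rule that every one should. Sex-linked genes matched in all 4 numbers: Xist was high (9.07 and 8.69) in both tissues of number 3 and below 3 in the others, and Y-linked Eif2s3y showed the opposite. A random numbering would match in 25% of cases. The block thus costs degrees of freedom whether or not it pairs embryos, and fits without it stand beside the counts. If a number holds several embryos or different ones, p-values measure the spread between these samples.

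Gene lists were tested with limma's camera on the same design with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists. In all, 38 lists were fixed from textbook knowledge, covering cell types near the aorta, signalling pathways and cell states, with 778 genes, of which 729 are in the table. A list needed at least 5 tested genes, which 36 had. The lists of liver parenchyma and pancreas had 4 and 2 tested genes and were not tested. Camera with an estimated correlation, fry and the number of members called when adjusted over the list alone stand beside it. An exact two-sided permutation of the list means over all 35 splits of the 8 arrays into groups of 4 was added after the data were examined. It ignores the replicate number and cannot give a p below 0.0286, which becomes 0.257 or more when adjusted over the 36 lists.

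Genes named in the text were set by rule. From genes past the threshold and changed the same way in all 4 replicate numbers, the 12 with the greatest difference in each direction were to be taken, leaving out predicted genes, microRNA, snoRNA and pseudogenes. As none passed, these are the 12 with the smallest unadjusted p in each direction among genes changed the same way in all 4 replicate numbers. Their agreement over the replicate numbers was thus a condition of being named and is not a result. Further, up to 3 members with the smallest p of each list described were taken, and always Kitl, Cxcl12, Bmp4, Runx1, Kit, Gata2, Gata3, Shh, Th, Hand2, Nog, Foxf1, Pax1, Sox9 and Wt1. The other genes named (Acan, Col11a1, Hox genes and T cell receptor segments outside those rules, Dad1, metalloproteinases, the liver markers, Zic1, and members of lists given as called) were chosen after their values were seen. The design, the lists, the rule and the alternatives were fixed before the data were examined, apart from those stated as added.

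Alternatives were no block, a random block (duplicateCorrelation), no filter and a stricter one (mean above the 75th percentile of row means), median centring, cyclic loess, quantile normalization, array weights, eBayes without trend or robust estimation, the mean of a gene's rows, leaving out each replicate number, a 2-fold minimum and an adjusted p of 0.1. Leaving out dorsal replicate 4 or ventral replicate 2 without the block was added after the data were examined. The tests were run on simulated data with this design (5 simulations over 12416 genes, 200 changed genes). The blocked fit recovered 30.8% of genes changed by 1 log2 unit and 79.2% of those changed by 2, with 3.6 false calls on average, and without the block 45.2% and 89.8% were recovered with 4 false calls. A list of 20 genes shifted by 0.5 was called in 5 of 5 simulations, and 0 of 30 unchanged lists in each. These simulated genes vary independently, unlike real lists. Figures were drawn with matplotlib 3.10.9.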

Results

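The series measured gene expression in tissue taken from above and below the dorsal aorta of mouse embryos of the C57Bl/6 strain at embryonic day 12.5, in the aorta-gonad-mesonephros region where blood stem cells first form. Dorsal tissue lay between the notochord and the aortic roof, and ventral tissue lay under the aorta. Both were isolated from cryosections by laser microdissection, from the same embryos. Each tissue was measured on 4 Affymetrix mouse Gene 2.0 ST arrays, labelled as biological replicates 1 to 4, so 8 arrays in all. RNA amounts were in the picogram range and were amplified before hybridisation. The values are log2 RMA intensities. They were available for 25429 rows, of which 24675 had 1 gene symbol, and 12416 genes lay above the array median on at least 4 arrays and were tested. Across these genes, arrays correlated at r = 0.907 to 0.957 within dorsal tissue, 0.907 to 0.948 within ventral tissue and 0.907 to 0.936 between the tissues (correlations across genes, which are not independent replicates). The number of arrays limits the precision of every difference given here. The series title names the subaortic niche of blood stem cells, and the comparison asks which genes separate the tissue under the aorta from the tissue above it. All differences are ventral minus dorsal on the log2 scale, and each "replicate number" joins the dorsal and the ventral array with that number.

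Several named genes on the dorsal side belong to the sclerotome, the part of the somite that forms vertebrae, although no single gene passed the test in the fit with the replicate number as a block. Their list was called by camera, limma's test of gene lists (adjusted p = 2.05e-18), but not with an estimated correlation between genes (adjusted p = 0.538). The lowest unadjusted p on the dorsal side belonged to Pax9 and Pax1, transcription factors of the sclerotome, with ventral minus dorsal differences of -2.05 (SE 0.21) and -2.28 (SE 0.24). Col2a1, the main collagen of cartilage, stood at 7.57 ± 0.62 in dorsal and 4.88 ± 0.22 in ventral tissue (SD, n = 4), a 6.44-fold difference. On the ventral side the widest gap was that of Trac, the constant region of the T cell receptor alpha chain, at 2.96 ± 0.33 in dorsal and 9.19 ± 1.41 in ventral tissue (SD, n = 4). Its dorsal values lay under the median of each array (medians 3.59 to 3.65), a range where background limits the size of a difference, so no fold is given. Tcf21, a transcription factor of visceral mesenchyme, differed by 3.30 (SE 0.38), from a dorsal mean of 3.11 that also lay under the array medians, and Gata6, a zinc finger transcription factor, by 1.59 (SE 0.18).

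With the replicate number as a block, limma called 0 genes at an adjusted p under 0.05 (Benjamini-Hochberg over 12416 genes), and the smallest adjusted p was 0.0717. At an unadjusted p under 0.05 there were 1026 genes, 507 higher and 519 lower in ventral tissue, where 620.8 would be expected by chance. At an adjusted p under 0.1 there were 13 genes. The 4 higher in ventral tissue were Trac, Syt1, Tcf21 and Gata6, and the 9 lower were Pax9, Pax1, Wwp2, Col2a1, Sox6, Fibin, Ogn, Crabp1 and AI646519. Without the block, limma called 4 genes at an adjusted p under 0.05: Trac was higher in ventral tissue (adjusted p = 0.014), and Col2a1 (0.0222), Wwp2 (0.0225) and Pax9 (0.0294) were lower. The random block called the same 4 genes. Without the block, leaving out ventral replicate 2 gave 0 genes and leaving out dorsal replicate 4 gave 9. Leaving out both arrays of replicate number 1 gave 9 genes in the blocked fit, and a filter for mean values above the 75th percentile of all rows gave 10.

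The other genes taken by smallest p on the ventral side did not pass the threshold, and each was higher in 4 of 4 replicate numbers, as the rule required. Fabp4, a fatty acid binding protein of adipocytes, macrophages and capillary endothelium, differed by 3.36 (SE 0.46) and Actg2, the gamma actin of visceral smooth muscle, by 1.99 (SE 0.32). Zfpm2, a cofactor of GATA factors, differed by 1.60, the metalloproteinase Adam12 by 1.49, the homeobox gene Hlx by 1.10, and the myeloid adaptor Tyrobp by 1.38. Syt1, a synaptic vesicle protein, differed by 1.64, Trappc2 by 1.71 and Ecm1 by 1.54. The dorsal means of Syt1 (3.54) and Trappc2 (3.51) lay under the array medians, which limits these differences. Genes taken on the dorsal side were lower in 4 of 4 replicate numbers by the same rule. Chad, a cartilage matrix protein, differed by -3.14 (SE 0.43), with a ventral mean of 3.15 under the array medians. The long non-coding RNA AI646519 differed by -3.05 (SE 0.39). Sox6, which acts in cartilage formation, differed by -1.82, the ubiquitin ligase Wwp2 by -2.11, Fibin by -2.31, osteoglycin (Ogn) by -1.73, the retinoic acid binding protein Crabp1 by -1.63, Sned1 by -1.43 and the receptor Fgfr2 by -1.26.

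**Figure D1:**
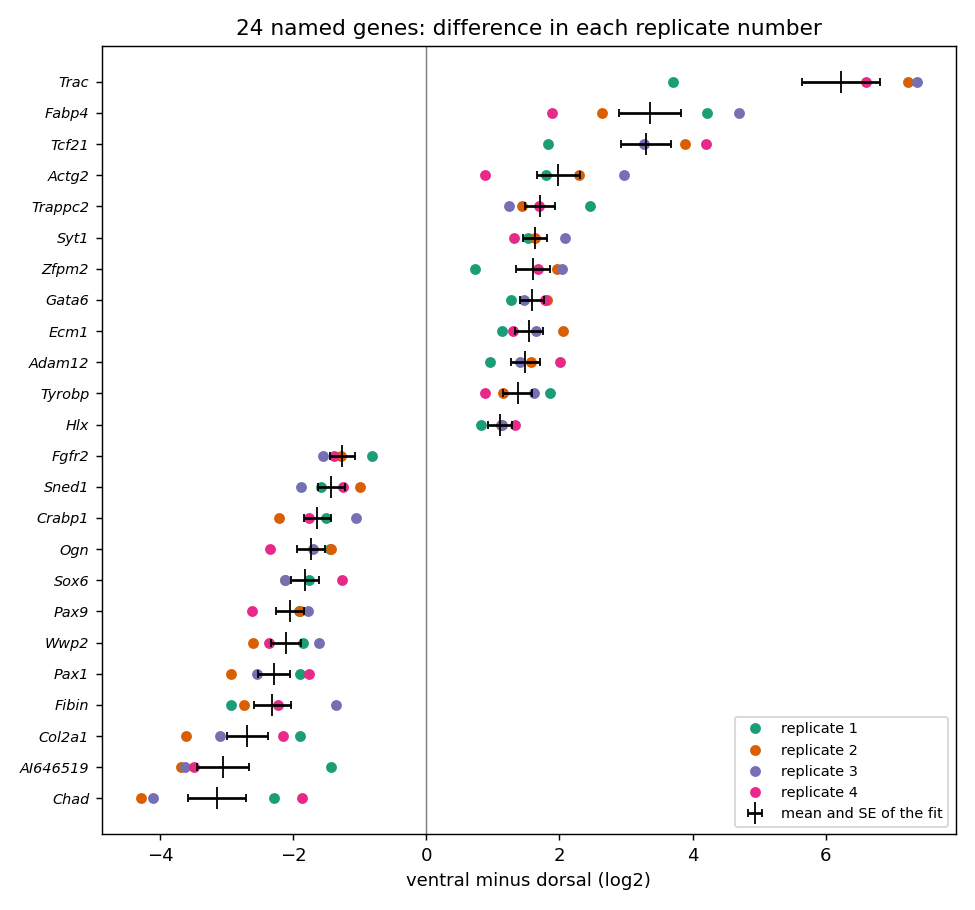
Ventral minus dorsal difference (log2, horizontal axis) of the 24 genes named by rule, with 1 point per replicate number and the mean with its SE from the blocked limma fit as a black mark. All points of a gene lie on the same side of 0 because the rule required it, and Trac spans 3.70 to 7.37.

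The sclerotome and cartilage list fell in ventral tissue. Its mean over 21 tested genes was 5.99 ± 0.53 in dorsal and 4.82 ± 0.15 in ventral tissue (SD, n = 4), a difference of -1.17 that was below 0 in 4 of 4 replicate numbers (from -0.79 to -1.59). Of the 21 genes, 19 were lower and 2 higher in ventral tissue. None was called over all genes tested, and 15 were called when adjusted over the list alone, all of them lower. Beside Pax1, Pax9, Col2a1 and Sox6 these included the proteoglycan Acan (-2.69, SE 0.47, with a ventral mean of 3.33 under the array medians), Col11a1 (-1.63) and Sox9, the main transcription factor of cartilage (-1.09, lower in 3 of 4 replicate numbers). In limma's camera test with a preset correlation of 0.01 the list had an adjusted p of 2.05e-18 over 36 lists. With an estimated correlation the adjusted p = 0.538 and the unadjusted p = 0.021. An exact two-sided permutation test of the list mean over the 35 splits of the 8 arrays gave an unadjusted p = 0.0286, the smallest it can give. That value was shared by 4 lists, and adjusted over the 36 lists it became 0.257, so no list passed that test. The exact p-values of other lists are unadjusted too. In all, camera called 8 of 36 lists, 3 as higher and 5 as lower in ventral tissue, and 0 with an estimated correlation (smallest adjusted p 0.538). In 5 lists, none of them called, the mean differed in sign from the median or from the direction of camera: secreted factors, TGF-beta, notochord, steroidogenic cells and interferon.

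Genes of smooth muscle and of macrophages were higher in ventral tissue in the camera test. The smooth muscle list differed by 0.60 (SD over replicate numbers 0.28), in 4 of 4 replicate numbers, with 12 of 13 tested genes higher (camera adjusted p = 0.000226, and adjusted p = 0.538 with an estimated correlation). Its exact permutation p was 0.0857. Actg2 was called when adjusted over the list alone, and 0 genes over all genes tested. Calponin (Cnn1) differed by 2.28 (SE 0.63) and Myl9, a myosin light chain, by 0.71 (SE 0.26), or by 0.39 without replicate number 3. The macrophage list differed by 0.49 (SD 0.48), in 3 of 4 replicate numbers, with 15 of 17 genes higher (camera adjusted p = 1.67e-05, and adjusted p = 0.549 with an estimated correlation). Its exact permutation p was 0.0857 as well. In replicate number 4 the difference was -0.19, with the macrophage list at 5.15 in dorsal replicate 4 (4.56 to 4.71 in the other dorsal arrays), the array where erythroid and liver genes were also high. Tyrobp was called when adjusted over the list alone and 0 genes over all genes tested. The complement component C1qb differed by 0.69 (SE 0.20) and the protease cathepsin S (Ctss) by 0.88 (SE 0.28).

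The sympathoadrenal list, genes of sympathetic neurons and adrenal chromaffin cells, differed by 0.52, with an SD over replicate numbers of 0.91. Camera called it as higher in ventral tissue (adjusted p = 0.00255, and adjusted p = 0.689 with an estimated correlation), while the exact permutation test gave p = 0.343. Of 20 genes, 15 were higher. Ddc, an enzyme of catecholamine synthesis (1.20, SE 0.27), and the receptor Ret (0.66, SE 0.16) were called when adjusted over the list alone, and 0 genes over all genes tested. Th, the first enzyme of that pathway, differed by 1.50 (SE 0.65) and ranged from -0.31 to 3.73 between replicate numbers, with 0.75 when number 1 was left out. The list lost its call without replicate number 3, when the difference was 0.18 with an adjusted p of 0.478, and without replicate number 2 the difference was 0.90 with an adjusted p of 7.22e-08.

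Camera called Hox genes of groups 1 to 8, which pattern the anterior and middle body axis, as lower in ventral tissue. The list differed by -0.45 (SD 0.40) in 4 of 4 replicate numbers, with 12 of 18 genes lower (camera adjusted p = 0.00224, and adjusted p = 0.689 with an estimated correlation). Its exact permutation p was 0.0286. Hoxc8 (-2.86, SE 0.43), Hoxc6 (-2.44, SE 0.45) and Hoxa7 (-0.70, SE 0.19) were called when adjusted over the list alone, and 0 genes over all genes tested. The difference was -1.01 in replicate number 1, -0.45 in number 2 and -0.16 in numbers 3 and 4, and without replicate number 1 it was -0.26 with an adjusted p of 0.615. Genes of spinal cord and neural progenitors moved with it in number 1, by -1.10 (-0.21 over all numbers, camera adjusted p = 0.107), with a list mean of 5.56 in dorsal replicate 1 and 3.95 to 4.25 in the other dorsal arrays. Zic1, a transcription factor of that list, differed by -3.82 in number 1. Hox genes of groups 9 to 13 differed by -0.27 (camera adjusted p = 0.0313, and adjusted p = 0.538 with an estimated correlation), with 7 of 10 genes lower, but the exact permutation p was 0.657. No gene of that list was called over the list alone or over all genes. Without the block the difference was the same with an adjusted p of 0.184. Without replicate number 4 it was -0.27 (adjusted p = 0.0648) and without number 3 it was -0.16 (adjusted p = 0.267). With no block it was -0.56 without dorsal replicate 4 (adjusted p = 0.0295) and -0.15 without ventral replicate 2 (adjusted p = 0.464).

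Camera also called genes of skeletal muscle and of cell proliferation as lower in ventral tissue, by small amounts. The skeletal muscle list differed by -0.33 (SD 0.46) with 10 of 12 genes lower (adjusted p = 0.0369, and adjusted p = 0.549 with an estimated correlation, exact permutation p = 0.257). Cardiac actin (Actc1), also made by young skeletal muscle, differed by -1.32 (SE 0.59), by -0.53 without replicate number 2 and by -1.91 without number 3. Without replicate number 2 that list differed by -0.11 (adjusted p = 0.37) and without number 4 by -0.33 (adjusted p = 0.0763). Its call was also lost with a random block and with the stricter filter. The proliferation list differed by -0.16 (SD 0.26) in 2 of 4 replicate numbers, with 21 of 29 genes lower (adjusted p = 0.0203, and adjusted p = 0.739 with an estimated correlation, exact permutation p = 0.371). Mki67, a marker of cycling cells, differed by -0.61 (SE 0.16). Without replicate number 2 or 3 the proliferation list differed by -0.0723 or -0.0899 (adjusted p = 0.265 or 0.323), and without number 4 by -0.24 (adjusted p = 0.00128). In both lists 0 genes were called over the list alone or over all genes tested. Fry, which asks whether the genes of a list move on balance in 1 direction, called 0 of 36 lists at an adjusted p under 0.05 (smallest 0.125, the sclerotome list) and 5 at an unadjusted p under 0.05. Its mixed test, which asks whether genes of a list change in either direction, called 18 of 36 lists.

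**Figure D2:**
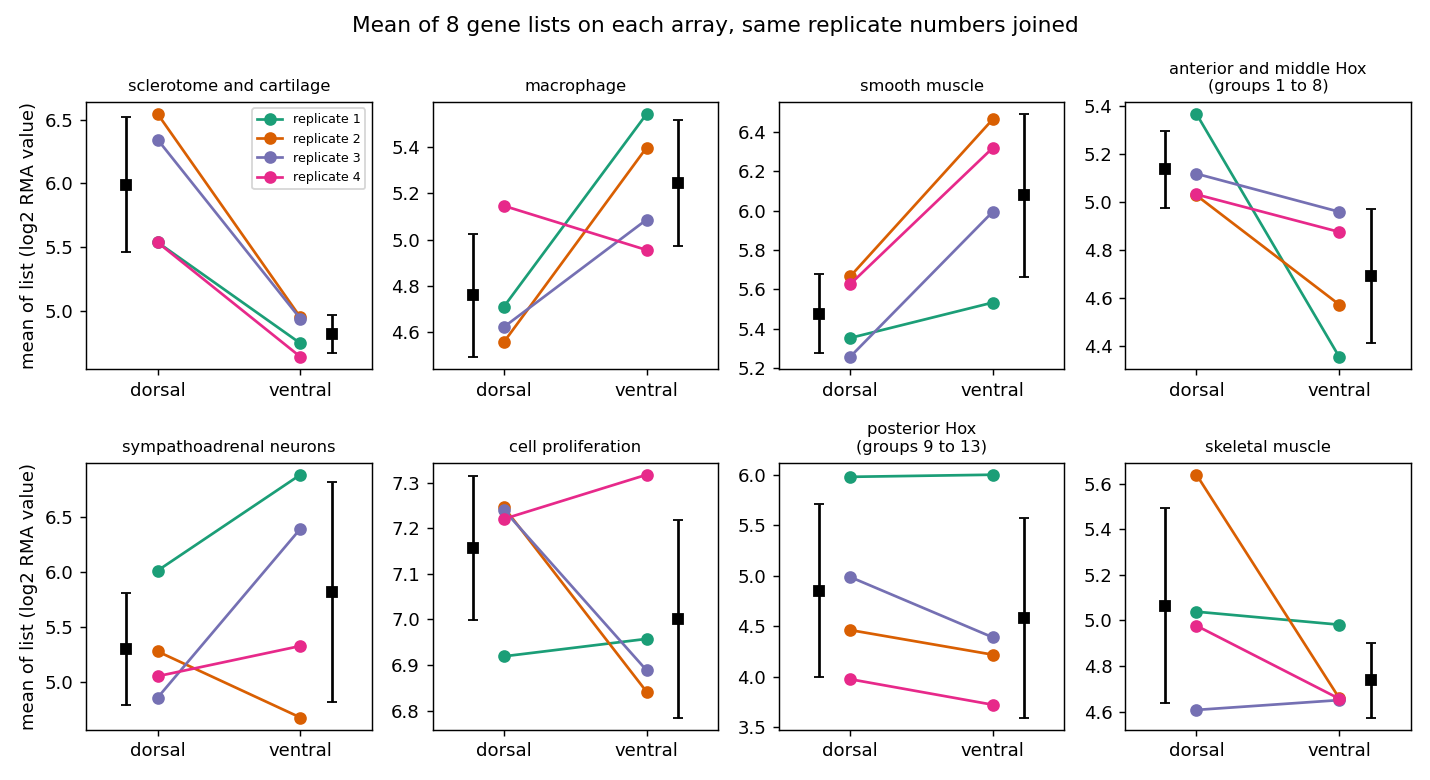
Mean log2 RMA value (vertical axis, a separate scale in each panel) of the 8 gene lists called by camera with a preset correlation, on each dorsal and ventral array, with lines joining the same replicate number and black squares for the mean with SD of 4 arrays. All 4 lines fall for the sclerotome and cartilage list, from a dorsal mean of 5.99 to a ventral mean of 4.82.

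Genes of visceral (splanchnic) and gut mesenchyme went both ways. The list differed by 0.44 in 4 of 4 replicate numbers, missed the camera threshold (adjusted p = 0.0681) and had an exact permutation p of 0.0286. Camera called it in 3 of 18 settings: a random block, no filter and the stricter filter. Over the settings its lowest adjusted p was 0.0022 and its widest difference 0.70. Adjusted over the list alone, 4 genes were called as higher (Tcf21, Gata6, Hlx and Isl1) and 2 as lower (Foxf2 and Zfhx3), and 0 over all genes tested. Foxf1, a Hedgehog target in this mesenchyme, differed by -0.44 (SE 0.35), and by -0.0322 without replicate number 3 and -0.78 without number 4. In the list of coelomic epithelium and mesothelium (0.44, camera adjusted p = 0.0591), the mesothelial factor Wt1 differed by 0.84 (SE 0.27) and Krt7 by 0.97 (SE 0.24), while Tbx18, also in the sclerotome list, differed by -1.19 (SE 0.21). Adjusted over the list alone, 3 genes were called as higher (Tcf21, Krt7 and Wt1) and 1 as lower (Tbx18), and 0 over all genes tested. Without replicate number 1 or 4 camera called that list (adjusted p = 0.0111 and 0.023). The Hedgehog list differed by -0.24 (adjusted p = 0.0591). Its member Ptch1, receptor and target of the pathway, differed by -1.69 (SE 0.26) in 4 of 4 replicate numbers and was the only member called when adjusted over the list alone. Gli1, another target, differed by -0.72 (SE 0.23) and the ligand Shh by 0.29 (SE 0.26). Without replicate number 4 the Hedgehog list was called at -0.35 (adjusted p = 0.0137), and without number 3 it was -0.16 (adjusted p = 0.293). It was called in 4 of 18 settings, the others being no filter, the stricter filter and array weights. Over all settings it ranged from -0.40 to -0.16.

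For secreted factors that act on blood stem cells, no shift in 1 direction was called. That list had a mean of 6.06 ± 0.20 in dorsal and 6.05 ± 0.22 in ventral tissue (SD, n = 4), a mean difference of -0.01 with a median of 0.00 on the other side of 0 (camera adjusted p = 0.615). Fry's mixed test of change in either direction called it (adjusted p = 0.0102), as it did 18 of 36 lists. Angpt1, the ligand of the receptor Tek, differed by -1.40 (SE 0.27) and Igf1 by 1.26 (SE 0.30), and these 2 genes were called in opposite directions when adjusted over the list alone, with 0 over all genes tested. Stem cell factor (Kitl) differed by 0.13 (SE 0.28), Cxcl12 by -0.15 (SE 0.16) and Bmp4 by 0.00 (SE 0.22). The means of Kitl (3.65 dorsal, 3.79 ventral) lay near the array medians, which limits its difference. With 1 replicate number left out, the list ranged from -0.10 to 0.0568, Kitl from -0.24 to 0.33, Cxcl12 from -0.30 to -0.0745 and Bmp4 from -0.20 to 0.17. In the BMP list (0.08, adjusted p = 0.63) the antagonist Grem1 (-0.94, SE 0.17) and Id4, an inhibitor of bHLH factors (-0.85, SE 0.15), were called as lower over the list alone, and 0 genes over all genes, while the antagonist Noggin (Nog) differed by 0.08 (SE 0.16).

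Genes of blood stem and progenitor cells differed by 0.06 as a list (SD 0.04, adjusted p = 0.615, 7 of 13 tested genes higher), and 0 were called over the list alone or over all genes. Of the 22 genes fixed for that list, 21 are in the table. Ptprc, Itga2b, Hlf and Procr are among those that lay under the filter on low values, so the list value does not cover them. The smallest unadjusted p-values in that list belonged to Mecom and Spi1. Mecom differed by -0.95 (SE 0.28), lower in 4 of 4 replicate numbers, and Spi1 by 0.41 (SE 0.15), higher in 4 of 4. Runx1, needed for blood stem cells to form, differed by 0.69 (SE 0.37), from -0.75 to 1.75 between replicate numbers. Kit differed by 0.27 (SE 0.21) and Gata2 by -0.06 (SE 0.21), and Gata3 and Hand2, factors of the sympathoadrenal lineage, by 0.12 (SE 0.22) and 0.70 (SE 0.38). The means of Gata2 (3.59 dorsal, 3.54 ventral) and the dorsal means of Spi1 (3.66) and Runx1 (3.70) lay at or near the array medians, which limits these differences. Hand2 differed by 0.27 without replicate number 1 and by 1.07 without number 2, Runx1 by 1.17 and 0.33 without number 1 and 3, and Kit by 0.0529 without number 4, while Gata2 and Gata3 turned direction when 1 replicate number was left out (-0.33 to 0.0794 and -0.0362 to 0.30). The arterial endothelial list differed by 0.21 in 4 of 4 replicate numbers (adjusted p = 0.0591, exact permutation p = 0.0286), and without replicate number 2 by 0.28 (adjusted p = 0.0377). Of its 13 tested genes, 10 were higher and 3 lower. Hey2, a Notch target of arteries, differed by 0.81 (SE 0.20) and Hey1 by 0.56 (SE 0.22). Gja5, of the same list, differed by -0.52 (SE 0.23) and was lower in 4 of 4 replicate numbers. The pan-endothelial list differed by 0.13 (adjusted p = 0.228), and without replicate number 2 by 0.31 (adjusted p = 0.00813). Of its 16 tested genes, 13 were higher and 3 lower. Kdr differed by 0.85 (SE 0.30) and Tek by -0.62 (SE 0.27). Erythroid genes, made by red cells in blood and in the fetal liver, differed by -0.17 with an SD of 0.69 (adjusted p = 0.301). Their difference was -1.19 in replicate number 4, where dorsal tissue reached a list mean of 8.24, and 0.17 without that number. Liver markers moved with them in that array: Apoa2 was at 10.10 in dorsal replicate 4 (4.14 to 4.54 in the other dorsal arrays) and 7.31 in ventral replicate 4, and Apoa1 was at 6.38 in dorsal replicate 4 (others 3.77 to 3.95). Without replicate number 1 the erythroid list differed by -0.33 and was called (adjusted p = 0.0355).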

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

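The tests of other explanations for Trac, the macrophage genes and the posterior Hox genes were chosen after the results were seen. The counts over other splits of the arrays were planned before.

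Without the block, only the real one of the 35 splits of the 8 arrays gave as many as 4 genes. The highest of the other splits gave 1. This share (0.0286) lies under 0.05, but it is the smallest these splits can give and is not adjusted. The splits also ignore the replicate number, so chance is not excluded for the count of genes called. That count was 0 with the block, and 0 without the block when ventral replicate 2 was left out. With the block, only 8 splits part every replicate number, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1026 genes, reached by 1 of the 8, and the highest other gave 733. Without the block the real split gave 992 genes at that unadjusted p. The split that exchanged ventral replicate 1 for dorsal replicate 4 gave more, 1001, so the real split did not stand out on that count. For the number of lists called by camera with a preset correlation, chance cannot be excluded. Without the block the real split called 7 lists, 14 of 35 splits called as many, and the highest other called 12. With the block the real split called 8 lists, and 2 of the 8 splits did, the highest other at 11. The split with 12 lists exchanged ventral replicate 1 for dorsal replicate 4, and the one with 11 exchanged both arrays of number 4. With the block, 5 of the 8 called lists had a smaller adjusted p than the same list in any of the other 7 splits: sclerotome (2.05e-18, smallest other 6.45e-06), smooth muscle (0.000226 and 0.0019), anterior and middle Hox (0.00224 and 0.00735), posterior Hox (0.0313 and 0.0446) and skeletal muscle (0.0369 and 0.0375). The macrophage, sympathoadrenal and proliferation lists had a larger p than in another split (for macrophage, 1.67e-05 against 6.27e-10). Without the block, of the 7 called lists 1 did so, the sclerotome list (1.76e-17, smallest other 7.80e-10). Its mean difference was the widest of the 35 splits, as was that of 3 other lists.

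In 10 of 228 groups of 4 arrays (94 named genes and 20 lists in each tissue), 1 array lay far from the other 3. Chance alone gives about 1 in 20 such groups, or 11.4. Dorsal replicate 4 was high in the erythroid list (8.24, others 6.13 to 6.34) and in the red cell gene Hemgn (8.16, others 3.58 to 3.86), and liver markers were high in the same array (Apoa2 at 10.10, others 4.14 to 4.54, and Apoa1 at 6.38, others 3.77 to 3.95), as was the macrophage list (5.15, others 4.56 to 4.71). Dorsal replicate 1 was low in the proliferation list (6.92, others 7.22 to 7.25) and in Foxf1 (4.38, others 5.52 to 5.74). Dorsal replicate 3 was high in the splanchnic list (5.20, others 5.02 to 5.05) and in Cnn1 (5.21, others 3.74 to 3.96). Ventral replicate 1 was high in the skeletal muscle list (4.98, others 4.65 to 4.66) and in Trappc2 (6.10, others 4.891 to 5.002). Ecm1 was high in ventral replicate 4 (7.47, others 6.24 to 6.34) and Sox17 in ventral replicate 2 (4.90, others 4.49 to 4.54).

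Trac was 6.23 log2 units higher in ventral tissue, a size limited by its dorsal level of 2.96 (2.75 to 3.44), under the array medians. T cells or their precursors in the ventral tissue are argued against, because 11 genes of T cells and their precursors, among them Cd3e, Cd3d, Zap70 and Rag1, had a median difference of 0.0452 (SD 0.0791) and ventral means of 4.31 or less, although 9 of the 11 lay under the filter on low values. Dad1, the gene next to Trac in assembly GRCm38.p6, differed by 0.0857 (95% interval -0.411 to 0.583). Only the order of the genes was used and not the strand they are read from. The level of Dad1 therefore cannot decide on transcription that reads through from it into Trac. For transcription through the J alpha and C alpha part of the locus without a joined V segment, the test does not decide. Traj11 differed by 4.16, but of 57 J alpha and 45 V alpha segments in the table, only 10 and 10 lay above the filter, and these differed by 0.66 and 0.12 on average (two-sided permutation p over segments 0.259). Over all of them the means were 0.36 and 0.05 (permutation p = 0.00111), with a J alpha median of 0.17 and 6 J alpha segments at 1 or more, and most lie near the floor. Segments of 1 locus are not independent replicates, cross-hybridisation of the Trac probes to another transcript was not tested, and a difference between the tissues in which cells transcribe the locus stays open as a hypothesis.

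Macrophage genes were 0.49 higher in ventral tissue. Circulating blood as the source of the whole shift is argued against only weakly, as far as erythroid genes follow it. The 6 erythroid genes of low baseline differed by -0.41 (SD over replicate numbers 0.74), below the macrophage shift by more than that SD. Replicate number 4 stood at -1.50. Outside it they differed by 0.0343, 0.0383 and -0.208, where the macrophage list differed by 0.83, 0.84 and 0.46. In those replicate numbers Hemgn (3.36 to 3.86) and Klf1 (3.79 to 4.36) lay near the array medians, where a rise would be compressed. The whole erythroid list was higher in ventral tissue there, by 0.32, 0.15 and 0.0467. With no block and without dorsal replicate 4 it differed by 0.33 (camera adjusted p = 0.0253), and the macrophage list by 0.61. Some more blood in the ventral tissue thus stays open. A lower share of sclerotome cells would raise markers of every other cell type alike if nothing else differed. Whether nothing else differed was not tested. The medians of the pan-endothelial, lymphatic endothelial and neural crest lists were 0.14, 0.03 and 0.17, below the macrophage median of 0.42, while that of smooth muscle was 0.43. The SD of the list difference over replicate numbers was 0.43, 0.12 and 0.50 in the first lists and 0.48 for macrophages, so these medians do not decide. The macrophage list exceeded the erythroid list by 0.65 (SD 0.25), in 4 of 4 replicate numbers. The gap was widest in number 4 (0.998), where erythroid genes were high in dorsal tissue, and was 0.52, 0.69 and 0.42 in the others. Since erythroid genes can vary with blood or liver in the cuts, that comparison cannot decide. A lower share of sclerotome cells stays open. A difference in macrophage number or state between the tissues stays open, and so does chance, as the other splits of the arrays show.

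Posterior Hox genes differed more between replicate numbers than between tissues. Their list mean was 5.98 and 6.00 in dorsal and ventral replicate 1 and 3.97 and 3.72 in replicate 4, and Hoxd13 was at 8.13 and 9.45 in replicate 1 and 3.35 and 3.37 in replicate 4. Of the 24 ways to number the ventral arrays, 1, the real one, gave a sum of products of the dorsal and ventral deviations as large as 2.48, although the next gave 2.39, and 0 of 1000 random lists of the same size and spread reached that sum (highest 1.50). The list was picked because of this pattern and its genes vary together, so neither value decides between explanations. Tissue taken at different levels of the body axis in different embryos and a technical difference between arrays of the same number both stay open, as position along the axis is not among the labels used here, and a difference in stage between embryos was not tested.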

How the results depend on the processing

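Settings were planned except those without dorsal replicate 4 or ventral replicate 2, which were chosen after seeing the data. Of 94 named genes, 86 kept their direction under every setting tried, and so did 16 of 20 lists. The share of genes is raised by how they were chosen. The 12 per direction had to move the same way in all 4 replicate numbers, so leaving out 1 number cannot turn them in the blocked fit. Most others had the smallest p of their list. Of the genes that turned, all but Klf1 and Hemgn were among those always named. The count of genes called was 0 with the replicate block, and 4 with no replicate block or a random replicate block. It was 10 with a stricter filter on low values, 13 at an adjusted p of 0.1, 0 to 9 without 1 replicate number (9 without number 1), and with no replicate block 9 without dorsal replicate 4 and 0 without ventral replicate 2. It stayed 0 under every other setting. The stricter filter tests fewer genes (6156), and of the other moves the cause was not tested. The count of lists called by camera was 8 with the block and 7 with no replicate block or a random one. It was 13 with no filter on low values, 0 with an estimated correlation and 0 with fry, 5 to 11 without 1 replicate number (5 without number 3, 11 without number 4), and with no replicate block 11 without dorsal replicate 4 and 8 without ventral replicate 2. Under the remaining settings it was 8 to 11. The cause was not tested. The mean of a gene's rows moves nothing, since each gene has 1 row. The sclerotome, macrophage and smooth muscle lists were called in 16 of 18 settings each, all but the estimated correlation and fry. Array 1, 2 and 4 of dorsal tissue, but not array 3, correlated best with the ventral array of their own number.

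Turns of direction were found in results that were not called with all arrays and the block. Of these, the erythroid list was called at -0.33 without replicate number 1 (adjusted p = 0.0355), and the pan-endothelial list at 0.31 without number 2 (adjusted p = 0.00813). The secreted factor list was 0.13 with the stricter filter and -0.10 to 0.0568 without 1 replicate number. The BMP list was -0.0190 to 0.16, the erythroid list -0.33 to 0.17 and the pan-endothelial list -0.00333 to 0.31 without 1 replicate number. Without 1 replicate number, Bmp4 ranged from -0.20 to 0.17, Gata2 from -0.33 to 0.0794, Gata3 from -0.0362 to 0.30, Kitl from -0.24 to 0.33, Nog from -0.0633 to 0.14 and Shh from -0.00196 to 0.58. Bmp4 was -0.00258 with median centring and -0.0250 with array weights. With no replicate block and without dorsal replicate 4, the erythroid list was 0.33 (adjusted p = 0.0253), the pan-endothelial list -0.0373, Bmp4 -0.0568, Gata2 0.0439, Kitl -0.11, Klf1 0.0243 and Hemgn 0.31. Without ventral replicate 2, Gata2 was 0.0133 and Nog -0.0298. The cause was not tested beyond the left-out arrays themselves. Signal over background limits genes near the array medians of 3.59 to 3.65, where differences are compressed.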

Other observations

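Members of the axon guidance and pericyte lists went both ways. Fry's mixed test called both, but it called 18 of 36 lists, so it does not set these lists apart. In the axon guidance list (-0.10, camera adjusted p = 0.439, fry mixed adjusted p = 0.00832) Slit2, a secreted repellent, differed by 1.58 (SE 0.30), while its receptor Robo2 differed by -1.74 (SE 0.40), Sema3a by -1.67 and Sema3e by -0.86, the last with a ventral mean of 3.29 under the array medians. Adjusted over the list alone, 1 gene was called as higher and 5 as lower, and 0 over all genes tested. In the pericyte list (0.14, camera adjusted p = 0.615, fry mixed adjusted p = 0.0040) Rgs5 differed by 2.48 (SE 0.55, from 0.49 to 4.03 between replicate numbers) and Mcam by 0.67, while the proteoglycan Cspg4 differed by -0.80 (SE 0.16), Foxc1 by -0.85 and Angpt1 by -1.40, with 2 genes called as higher and 3 as lower over the list alone and 0 over all genes. The list differed by 0.31 without replicate number 2 and by 0.0774 without number 1, and the axon guidance list by -0.0544 without number 1. In ventral replicates 1 to 4 Rgs5 stood at 8.35, 4.52, 7.21 and 5.60, and the sympathoadrenal genes stood at 8.12, 4.23, 6.55 and 4.63 (Th) and 9.79, 4.41, 7.76 and 5.93 (Chgb), a likeness that was not tested over 4 arrays. Aldh1a1, an enzyme of retinoic acid synthesis, differed by 2.16 (SE 0.60) and ranged from 0.53 to 4.37 between replicate numbers.

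The hypotheses here were formed and tested after the values were seen. Metalloproteinases stood near the top of the ventral side, with Adam12 at 1.49, Adamts5 at 1.62, Adamts1 at 1.31, Adamts9 at 1.26, Adam10 at 0.99 and Mmp14 at 0.84. Over 29 tested ADAM, ADAMTS and MMP genes, 21 were higher in ventral tissue. These 6 genes and Adam19 prompted the hypothesis that the family is higher, so it was tested on the other 22, which differed by 0.0750 on average (SD over replicate numbers 0.12), with 14 higher. Camera with a preset correlation gave p = 0.365, and p = 0.579 with an estimated correlation. The genes left out were the highest of the family, which pulls the mean of the rest down. The test therefore cannot decide whether the family as a whole is shifted.

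Hoxc6 and Hoxc8 had the lowest differences among 28 tested Hox genes, and the hypothesis that the HoxC cluster is lower in ventral tissue than the other 3 clusters was tested. Without that pair, which prompted it, the other 4 HoxC genes differed by -0.33 on average, between -0.59 and 0.13. The 22 genes of the other clusters differed by -0.19, and HoxB by -0.33 (exact two-sided permutation p over genes 0.498). Leaving out the lowest pair pulls the mean of the rest up, so the test cannot decide whether the cluster as a whole is lower. Neighbouring genes of a cluster are not independent.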
